A study of Homo sapiens with 16 samples.

How the data were processed

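U937 cells, an established human myeloid leukemia line of monocyte type, were profiled on 16 Affymetrix arrays, 1 array per culture, in 4 groups of 4. The groups were sham treatment, LysoPPC (a lysophosphatidylcholine carrying a palmitoyl chain, at 10 µM), FSL-1 (a synthetic diacylated lipopeptide and ligand of the TLR2/TLR6 receptor pair, at 1 µg/ml) and LysoPPC followed by FSL-1. The series design calls the 4 cultures of a group biological replicates. Per the labels' protocols, pretreatment lasted 1 h, FSL-1 was then present for 2 h, and RNA was isolated at 3 h. The label of the LysoPPC group gives only a 1 h treatment, so whether the lipid was removed before isolation is not given in the sources used here. RNA was amplified and biotin-labelled with a whole-transcript kit, per the labels' protocols.

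The deposited values are RMA intensity values, background-corrected, normalized between arrays and summarised per probe set by the authors with Affymetrix Expression Console 1.3.1.187, per the submitters' processing notes. They ran from 0.996 to 11071 and were therefore on a linear scale, whereas the planned design had assumed log2 values; log2 was taken here with no pseudocount, and the fitted model was otherwise as planned. No scanner files, probe-level data or genome build were used here, so no coordinates are given. Arrays have no count depth; their number limits the precision. The median intensity of the arrays lay between 2.69 and 2.79, so no further scaling was applied. Because RMA had already forced the arrays to a common distribution, a shift of all transcripts together could not be seen in these values.

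The table held 53617 probe sets. A probe-to-gene table gave exactly 1 symbol for 23871 of them and several for 1842, and did not list 27904, which are unnamed here. Symbols were updated through Entrez identifiers, which matched for 22569 probe sets and renamed 90. A probe set entered the tests if at least 4 of the 16 arrays lay above the median of all values, 1.459 on the log2 scale; 16446 named probe sets did so. A gene with several probe sets, as for 632 genes, was represented by the one with the highest mean, which left 15424 genes. Probe sets with no symbol or several were tested apart from these.

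Group means were fitted to all 16 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with 1 spread shared by the groups and 12 residual degrees of freedom. All 6 contrasts were two-sided, with Benjamini-Hochberg adjustment within each contrast and a threshold of 0.05. They were FSL-1 minus sham, LysoPPC minus sham, LysoPPC followed by FSL-1 minus FSL-1, the interaction (the FSL-1 response in LysoPPC-pretreated cells minus that in sham-pretreated cells), and both agents minus LysoPPC or minus sham. FSL-1 responders were the genes past the threshold for the FSL-1 effect averaged over both pretreatments, a choice that does not favour either sign of the interaction. Over them the slope through 0 of the response with LysoPPC on the response without it was ranked among 100 groupings by the LysoPPC label, the real one included.

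The contrasts, the alternatives, 28 gene lists and the rule for named genes were written before the data were examined. The rule took, per contrast, up to 8 rising and 8 falling genes with the largest change among those past the threshold whose 4 and 4 array values did not overlap. It added up to 4 members of each list past the threshold, and TNF, IL1B, CXCL8, CCL3, CCL4, NFKBIA, TNFAIP3, TLR2, TLR6 and GPR132 whatever their result. Where no gene passed, the 3 with the smallest unadjusted p were taken. Of the 28 lists, 27 had measured members; mitochondrial-encoded transcripts had none and were not analysed here. List members past the threshold were counted, and the lists were tested with camera at a preset correlation of 0.01, adjusted over 108 tests (27 lists in 4 contrasts). An estimated correlation, fry (which asks whether the genes of a list move one way on balance) and an exact permutation test of the list mean per array (two-sided, 4 against 4, smallest possible p = 0.0286) were run beside it.

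The procedure was tested on simulated data with 200 changed genes among 15424. At a change of 1 on the log2 scale it recovered 83.6% of them for FSL-1 minus sham, 91% for LysoPPC minus sham, 83.6% for both agents minus FSL-1 and 58.2% for the interaction. At 0.5 the shares were 29.9%, 19.4%, 35.8% and 10.4%. A planted slope of 0.7 came back as 0.687 and one of 1 as 0.977. The simulated noise was independent between genes, whereas 1 component held 34.2% of the variance of the real deviations from group means. With fewer changed genes the adjustment is also stricter. The recovered shares may therefore be too high for these arrays.

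Alternatives covered the filter (none, or the 70th percentile), quantile normalization again, median centring, cyclic loess, the replicate number as a fixed or random block, only the arrays compared, eBayes without trend or robust, array weights, the mean of a gene's probe sets, adjustment over all probe sets, and each array left out in turn. After the data were seen, a floor of 4 on the log2 scale, the LysoPPC effect averaged over both FSL-1 conditions, and the gene lists without sham replicate 1 were added. No arrays had identical columns: the closest pair, from different groups, differed by an SD of 0.373 on the log2 scale.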

Results

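Expression was measured on 16 arrays of U937 cells, a human myeloid leukemia line. The cells received sham treatment, the lysophospholipid LysoPPC, the TLR2/TLR6 ligand FSL-1, or LysoPPC for 1 h followed by FSL-1 for 2 h, with 4 cultures each. After log2 transformation of the deposited RMA intensities 15424 genes were tested. Values are log2 intensities as mean ± SD with n = 4, and differences are log2 fold changes with their standard error (SE) from limma. The first principal component held 28.1% of the variance over genes and set sham replicate 1 apart, at -45.2, from the other sham arrays at 10.5 to 21.8. That array correlated with its own group at a median r of 0.970 across genes, while the other 15 arrays lay between 0.987 and 0.992 (genes are not independent replicates). The second component, with 13.2%, held the FSL-1-treated arrays at -0.70 to 14.8 and the arrays without FSL-1 at -18.3 to -4.64.

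**Figure D1:**
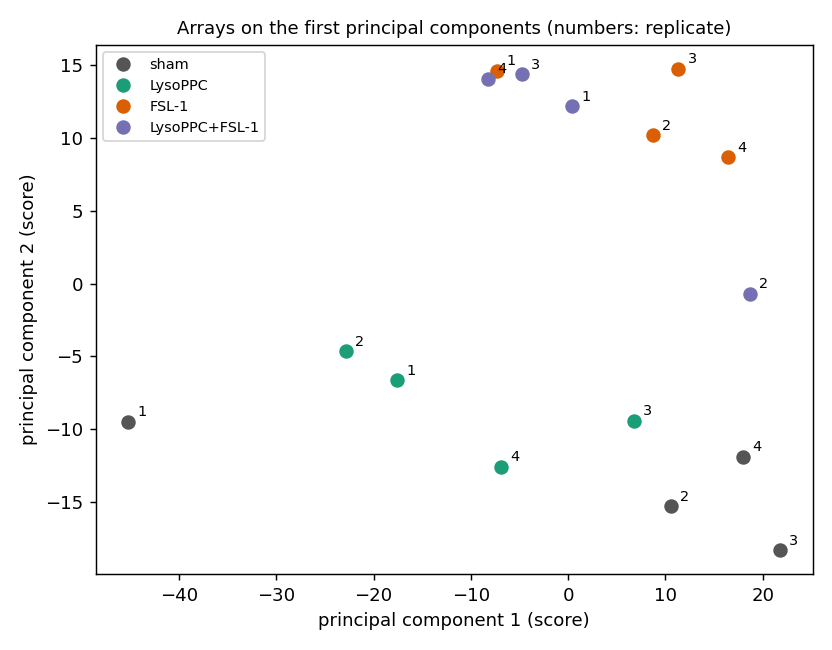
Scores of the 16 arrays on the first principal components of log2 intensity (horizontal axis, component 1; vertical axis, component 2; colours, groups; numbers, replicates). Sham replicate 1 lies at -45.2 on component 1, and LysoPPC+FSL-1 replicate 2 at -0.70 on component 2, below the other FSL-1-treated arrays.

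The first comparison asked how the cells respond to FSL-1. The chemokine CXCL10 (probe set 16977052) rose from 1.42 ± 0.24 (SD, n = 4) in sham cells, below the median of all values at 1.46, to 6.90 ± 0.32 (SD, n = 4). The hyaluronan-binding protein gene TNFAIP6 (16886491) rose by 5.199 (SE 0.24, adjusted p = 3.1e-10). TNFAIP3 (17012946), which encodes the NF-kappaB inhibitor A20, rose by 3.88 (SE 0.18), MIR146A, the precursor of a microRNA that restrains Toll-like receptor signalling, by 3.83 (SE 0.17), and the pentraxin PTX3 by 3.19 (SE 0.22). NFKBIA, which encodes the inhibitor IkappaB alpha, rose from 6.12 ± 0.32 (SD, n = 4) to 8.99 ± 0.04 (SD, n = 4), a change of 2.87. NFKBIZ rose by 2.74 (SE 0.20) and TNF by 2.69 (SE 0.22, adjusted p = 5.7e-07). Values of the 4 FSL-1 arrays did not overlap with those of the 4 sham arrays for any of these genes.

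In all, 107 genes passed the threshold in FSL-1 minus sham, 99 higher and 8 lower; 52 were higher by at least 2-fold and 0 lower by that much in limma's fit. The lower genes changed little. The largest falls were those of the hematopoietic transcription factor gene LYL1 (-0.65, SE 0.11, adjusted p = 0.0035), the nucleotide receptor gene P2RY2 (-0.59), the proto-oncogene MYC (-0.56, adjusted p = 0.0099) and ZFP36L2 (-0.50), which encodes an mRNA-destabilising protein. Without sham replicate 1, 178 genes passed, 138 higher and 40 lower, 104 of them among the 107; with array weights 205 passed, and with the spread taken from these 8 arrays alone 66, 65 higher and 1 lower. In the last fit LYL1, P2RY2 and MYC did not pass (adjusted p = 0.0881, 0.137 and 0.109), the highest values over their alternatives, whose lowest were 8.1e-04, 0.0034 and 0.0021. ZFP36L2 did not pass without sham replicate 2 or 4 or FSL-1 replicate 3 (adjusted p = 0.0581, 0.0608 and 0.0631; 8.6e-04 to 0.088 over all alternatives).

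Of the NF-kappaB pathway and feedback list, 18 of 36 measured members rose and 0 fell (24 rose when adjusted over the list alone), with a mean change of 1.00. Beside those named above, IER3, an early response gene of cell survival, rose by 2.38 (SE 0.19). Its 10 probe sets disagreed: 4 of them, near the background at a mean level of 1.52, gave 0.24 and the others 1.94 to 2.38, while the 8 probe sets of TNF gave 2.69 to 2.91. Several probe sets of each gene held identical values and are not separate measurements. The camera test gave adjusted p = 1.8e-57, and adjusted p = 1.5e-06 with an estimated correlation. Of 30 cytokines and chemokines, 7 rose and 0 fell (9 when adjusted over the list alone), with a mean change of 0.50. They included the monocyte chemoattractant CCL2, which went from 5.56 ± 0.49 to 8.05 ± 0.11 (SD, n = 4), IL1B (1.53, SE 0.17), CCL20 (1.29, SE 0.18) and CCL3 (1.04, SE 0.18). The camera test of this list gave adjusted p = 1.2e-11, and adjusted p = 0.0055 with an estimated correlation. CXCL8 stood at 1.192 (adjusted p = 0.149) and CCL4 at 1.62 (adjusted p = 0.335, SD 1.13 in FSL-1 cells), so neither passed; without LysoPPC+FSL-1 replicate 2 CXCL8 passed (adjusted p = 0.0274; 0.0274 to 0.396 over all alternatives).

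Of 34 immediate early and MAPK feedback genes, 6 rose and 1, MYC, fell (7 and 3 when adjusted over the list alone). IER5 rose by 1.15, the MAP kinase phosphatase gene DUSP10 by 1.04 and the transcription factor gene KLF6 by 0.88; DUSP4 rose by 0.94 and lost its call without FSL-1 replicate 3 (adjusted p = 0.0538; lowest over all alternatives 0.0037). The list gave camera adjusted p = 0.0105, adjusted p = 0.874 with an estimated correlation, and 0.382 without sham replicate 1. Of 28 chemokine and cytokine receptors, 4 rose and 0 fell (6 and 1 when adjusted over the list alone): the complement receptor gene C3AR1 by 1.78, the platelet-activating factor receptor gene PTAFR by 0.75, IFNGR2 by 0.69 and CXCR4 by 0.44. IFNGR2 was not past the threshold without FSL-1 replicate 2, 3 or 4 (adjusted p = 0.0802, 0.0549 and 0.0705), nor CXCR4 without FSL-1 replicate 2 (adjusted p = 0.0603); over all alternatives they ran from 0.0026 to 0.219 and from 0.002 to 0.189. The camera test of the receptors gave adjusted p = 0.0105, adjusted p = 0.362 with an estimated correlation, and 0.213 without sham replicate 1. Of 28 integrated stress response and ATF4 target genes 1 rose, the mTOR inhibitor gene DDIT4 (0.86), and 3 when adjusted over the list alone. DDIT4 did not pass with the spread of these 8 arrays alone (adjusted p = 0.064, from 0.0041 over all alternatives). For the list camera gave adjusted p = 0.047, adjusted p = 0.874 with an estimated correlation, and 0.216 without sham replicate 1.

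Among 34 interferon-stimulated genes CXCL10 and the RNA sensor gene IFIH1 (1.24, SE 0.21) rose and 0 fell (3 rose when adjusted over the list alone). The mean change of the list was 0.23 but its median -0.0005, of opposite sign, and camera gave adjusted p = 0.169; fry gave adjusted p = 0.0022. TLR2 itself was the 1 of 15 TLR2 receptor and adaptor genes that passed (2 when adjusted over the list alone), with 3.74 ± 0.42 in sham and 4.87 ± 0.30 in FSL-1 cells (SD, n = 4; adjusted p = 0.0456). The adjusted p of TLR2 lay close to the threshold. Its call was lost when any one of 11 arrays was left out, that is, all but sham replicate 1, LysoPPC replicates 1 and 2, FSL-1 replicate 4 and LysoPPC+FSL-1 replicate 2, with adjusted p up to 0.178 without sham replicate 3 (0.0027 to 0.178 over all alternatives), while the difference, 1.13 with all arrays, stayed between 1.02 and 1.14 in those 11 fits. With all arrays it was lost with no intensity filter, median centring, cyclic loess and adjustment over all probe sets (adjusted p = 0.0559, 0.0512, 0.0511 and 0.1075). It was also lost with the replicate number as a fixed block (adjusted p = 0.0642) and with the spread of these 8 arrays alone (0.0938). TLR6 did not reach the intensity filter and was not tested. In 6 other lists 1 member rose and 0 fell: the acyl-CoA synthetase gene ACSL1 (1.304) among 13 genes of fatty acid synthesis, the lysophosphatidylcholine transporter gene MFSD2A (1.32) among 21 of lysophospholipid receptors and metabolism, SQSTM1 (0.69) among 19 NRF2 targets, SLC2A6 (1.06) among 27 of hypoxia and glycolysis, NINJ1 (0.90) among 15 of the NLRP3 inflammasome and pyroptosis, and the caspase-8 regulator gene CFLAR (0.93) among 24 of apoptosis. SQSTM1 did not pass without FSL-1 replicate 1, 2 or 4 (adjusted p = 0.0643, 0.0685 and 0.0788; 0.0078 to 0.0881 over all alternatives), nor NINJ1 with the spread of these 8 arrays alone (adjusted p = 0.126, from 0.0012 over all alternatives). Adjusted over the list alone, 1 gene rose in each of these lists, except 2 in the NLRP3 list, and 1 fell in the apoptosis list. None of the 6 lists met the threshold with camera, with adjusted p from 0.0904 to 0.930. Mean and median differed in sign for fatty acid synthesis (0.05 and -0.03), hypoxia and glycolysis (0.06 and -0.0046) and the NLRP3 list (0.06 and -0.06). GPR132, a receptor once linked to lysophosphatidylcholine, stood at 0.25 (SE 0.18, adjusted p = 0.813).

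**Figure D2:**
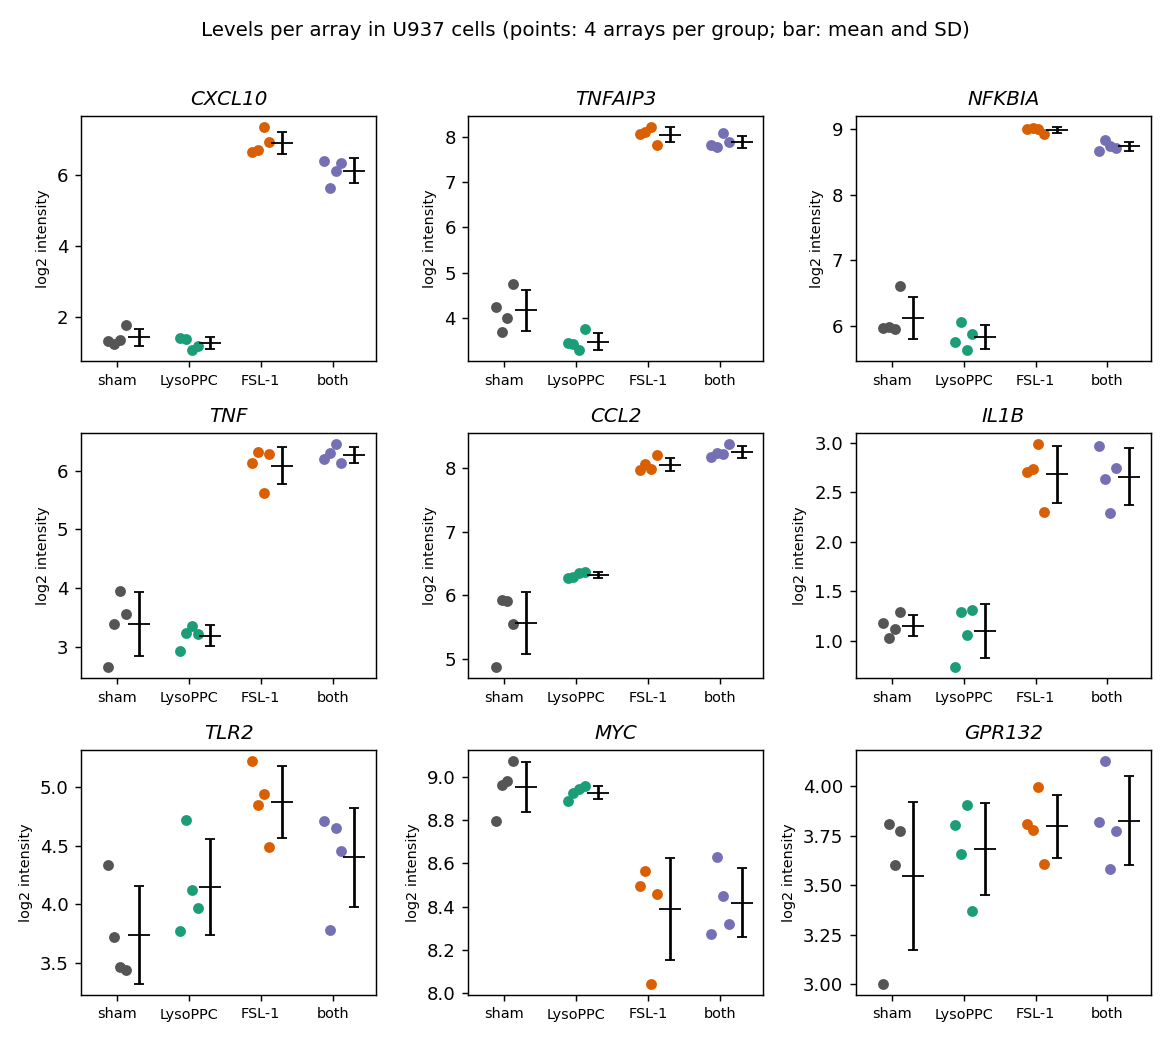
Level of 9 genes on each array (vertical axes, log2 intensity, each with its own range that does not start at 0; points, arrays; bars, mean and SD of 4 arrays). CXCL10 lies near 1.42 in sham, 1.25 in LysoPPC, 6.90 in FSL-1 and 6.12 in LysoPPC+FSL-1 cells (both).

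No member passed in FSL-1 minus sham among 20 genes of cholesterol synthesis, 9 LXR targets, 19 PPAR targets, 21 genes of the unfolded protein response, 14 of the heat shock response, 25 of monocyte maturation, 34 of the cell cycle, 9 histone genes and 26 ribosomal protein genes. Adjusted over the list alone, 2 rose in cholesterol synthesis, 1 in the unfolded protein response and 0 in the others. The camera adjusted p of these lists ran from 0.421 to 0.995. Without sham replicate 1, 3 cholesterol synthesis genes were higher and 1 monocyte maturation gene lower, and no member of the others passed. Markers of other cells, of which 6 T and NK lymphocyte, 7 B lymphocyte, 5 erythroid and platelet, 6 fibroblast and endothelial and 5 epithelial genes were measured, had mean changes of -0.06, 0.05, 0.10, -0.10 and -0.13 and no member past the threshold.

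The second comparison asked what LysoPPC does on its own. No gene passed in LysoPPC minus sham with limma (0 of 15424; lowest adjusted p = 0.677), while 983 had an unadjusted p under 0.05, where chance alone gives 771. The genes with the smallest p were the small nucleolar RNA SNORD78 (8.96 ± 0.13 in sham and 8.47 ± 0.11 in LysoPPC cells, SD, n = 4; difference -0.49), SPIN1 (0.51) and the BCL2 family gene BCL2A1 (0.70), all with adjusted p = 0.677. The chemokine gene CCL2 stood at 0.76 (adjusted p = 0.677), TNFAIP3 at -0.69 (SE 0.18, adjusted p = 0.717), NFKBIA at -0.30, TNF at -0.20, IL1B at -0.05, CCL3 at -0.04, CXCL8 at -0.01, CCL4 at 0.07, GPR132 at 0.14 and TLR2 at 0.40. For 96.5% of the genes the 95% confidence interval of the difference lay within 1 of 0 on the log2 scale. Without sham replicate 1, 2806 genes had an unadjusted p under 0.05. A single gene then passed, the DNA repair gene FANCI (1.32, adjusted p = 0.0159), chosen for naming after its value was seen. The count of 0 holds for the labels as given. With sham replicate 1 and LysoPPC replicate 3 exchanged, which is not excluded below, 1339 genes passed.

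Adjusted over the list alone, 1 cytokine gene, 1 interferon-stimulated gene and 1 NF-kappaB gene were higher and 1 NF-kappaB gene lower with LysoPPC. Of the lists, cholesterol synthesis and SREBP2 targets alone met the threshold in LysoPPC minus sham, with 0 of 20 members past it (2 higher when adjusted over the list alone), a mean level of 6.47 ± 0.03 in sham and 6.62 ± 0.06 in LysoPPC cells (SD, n = 4) and camera adjusted p = 0.047. The exact permutation test of the list mean gave p = 0.0286, the smallest it can give and not adjusted over lists. The call was lost under 4 of 5 alternatives, with adjusted p = 0.362 with an estimated correlation, 0.146 with fry, 0.0742 with no intensity filter and 0.240 without sham replicate 1, and held under the other (0.0421 to 0.362 over all alternatives). Without sham replicate 1, 0 members of this list passed in LysoPPC minus sham. In the same fit 3 members were higher in FSL-1 minus sham and 2 in both agents minus sham.

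The third comparison asked what pretreatment changes in FSL-1-stimulated cells. No gene passed in LysoPPC+FSL-1 minus FSL-1 with limma (0 of 15424; lowest adjusted p = 1.00), with 492 genes at an unadjusted p under 0.05 against 771 by chance. The smallest p were those of FAM66D (0.50), MIR2113 (0.87) and the chemokine gene CCL1 (0.93). In FSL-1 cells FAM66D (0.96 to 1.27) and MIR2113 (1.24 to 1.45) lay below the median of all values, 1.459, and CCL1 (1.78 to 2.00) little above it. TNF differed by 0.18 (95% interval -0.27 to 0.64), IL1B by -0.02 (-0.38 to 0.33), CXCL8 by 0.53 (-0.14 to 1.20), CCL3 by -0.03 (-0.42 to 0.35), CCL4 by 0.76 (-0.34 to 1.87), NFKBIA by -0.25 (-0.52 to 0.02), TNFAIP3 by -0.16 (-0.53 to 0.21), TLR2 by -0.47 (-1.003 to 0.06) and GPR132 by 0.03 (-0.35 to 0.41). The 95% interval lay within 1 of 0 for 97.5% of the genes. No list met the threshold with camera; adjusted over the list alone, 1 cytokine gene and 1 interferon-stimulated gene were higher, and 1 interferon-stimulated gene and 2 immediate early genes lower. Single arrays moved this count: without sham replicate 4 MIR2113 passed (0.87, adjusted p = 0.026), and without LysoPPC+FSL-1 replicate 3 CCL1 (1.20, adjusted p = 0.0159) and WASH3P (-1.14, adjusted p = 0.0188) did; on these 8 arrays alone the small nucleolar RNA SNORA68 passed (-0.56, adjusted p = 0.0419). WASH3P and SNORA68 were chosen for naming after their values were seen.

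Whether the FSL-1 response itself differed with pretreatment was tested by the interaction. No gene passed with limma (0 of 15424; lowest adjusted p = 1.00; 672 at an unadjusted p under 0.05, against 771 by chance). Leaving out sham replicate 1 put 1496 genes at an unadjusted p under 0.05, and again no gene passed. No list met the threshold with camera, and adjusted over the list alone 1 gene, of cholesterol synthesis, passed, with a lower response. The smallest p belonged to the chaperonin gene CCT4 (-0.36, SE 0.08), PITRM1-AS1 (-0.80, SE 0.19) and MIR3935 (0.75, SE 0.18). TLR2 gave -0.88 (95% interval -1.63 to -0.13, adjusted p = 1.00), and TNF gave 0.39 (-0.26 to 1.03). The median half-width of the 95% interval was 0.445, and for 88.0% of the genes the interval lay within 1 of 0.

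Averaged over both pretreatments, FSL-1 changed 183 genes, 163 higher and 20 lower. Among these responders the response with LysoPPC followed the response without it with a slope through 0 of 0.972 and a correlation across genes of 0.961 (genes are not independent replicates). Choosing genes on the average of both responses favours those in which they go the same way. The correlation was therefore partly fixed beforehand. The interaction had the opposite sign to the response in 92 of the 183 genes, or 50.3%. In 100 groupings by the LysoPPC label, the real one included, the slope lay at least as far from 1 in 67. By these arrays 0.972 was therefore not distinguishable from 1. As examples, the paired values were 5.48 without and 4.87 with LysoPPC for CXCL10, 5.199 and 4.93 for TNFAIP6, 3.88 and 4.41 for TNFAIP3, and 2.69 and 3.08 for TNF.

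**Figure D3:**
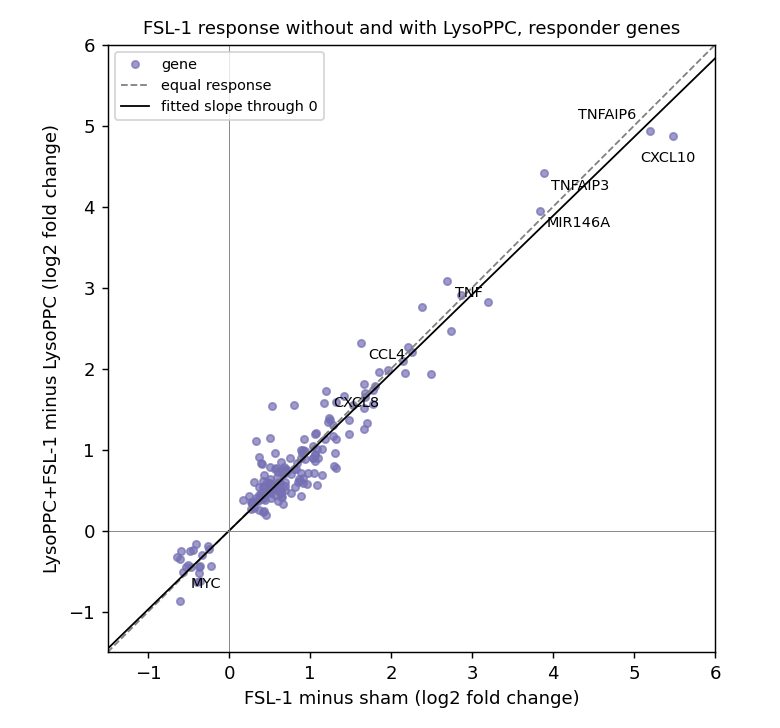
Log2 fold change on FSL-1 of 183 responder genes in sham-pretreated cells (horizontal axis) and in LysoPPC-pretreated cells (vertical axis); points are genes, the dashed line marks equal responses and the solid line the fitted slope through 0. The points follow a slope of 0.972.

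In LysoPPC-pretreated cells alone, FSL-1 raised 92 genes and lowered 2 against LysoPPC, 94 in all, with 46 higher by at least 2-fold. TNFAIP6 rose by 4.93 (SE 0.24), CXCL10 by 4.87 (SE 0.19), TNFAIP3 by 4.41 (SE 0.18), MIR146A by 3.95 (SE 0.17) and TNF by 3.08 (SE 0.22). The chemokine CXCL8 rose by 1.73 (adjusted p = 0.00999), but not past the threshold without LysoPPC replicate 4 (adjusted p = 0.0536, from 3.4e-04 over all alternatives). MIR657 (-0.93, adjusted p = 0.0112) and MYC (-0.51, adjusted p = 0.0278) fell; without LysoPPC+FSL-1 replicate 1 neither passed (adjusted p = 0.0525 and 0.133, the highest over their alternatives, whose lowest were 0.0046 and 0.0036), nor did MYC without 6 other arrays, namely each LysoPPC array and LysoPPC+FSL-1 replicates 3 and 4. CCL4 stood at 2.32 (adjusted p = 0.0591; 0.0028 to 0.244 over all alternatives) and passed without sham replicate 1, FSL-1 replicate 2 or 4 or LysoPPC+FSL-1 replicate 4 (adjusted p = 0.0445, 0.0318, 0.0488 and 0.0028). TLR2 stood at 0.25 (adjusted p = 0.993). Of the lists, 17 of 36 NF-kappaB genes, 7 of 30 cytokines and chemokines, 6 of 34 immediate early genes and 3 of 28 chemokine and cytokine receptors rose (22, 11, 9 and 4 when adjusted over the list alone), and 1 immediate early gene, MYC, fell (2 when adjusted over the list alone). This comparison shares no array with FSL-1 minus sham, and 76 of the higher genes were higher in both, where independent lists of 99 and 92 genes would share 0.591; of the others, 22 of 23 and 16 of 16 had the same sign in the other comparison. Of 8 and 2 lower genes 1, MYC, was lower in both (0.001 for independent lists), and 5 of the 7 and 0 of the 1 others had the same sign. That a gene passed in one and not in the other does not by itself show a difference between them. The interaction, which tests it, called 0 genes, and this does not show the responses to be equal.

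Both agents together raised 100 genes and lowered 6 against sham, 106 in all. TNFAIP6 (4.71, SE 0.24), CXCL10 (4.70, SE 0.19), MIR146A (3.73, SE 0.17) and TNFAIP3 (3.72, SE 0.18) changed most, followed by TNF (2.88), PTX3 (2.85), CCL2 (2.69) and NFKBIA (2.62). LYL1 fell to 6.54 ± 0.07 from 7.15 ± 0.16 (SD, n = 4). Of 36 NF-kappaB genes 19 rose, of 30 cytokines and chemokines 9, of 34 immediate early genes 5, and of 28 chemokine and cytokine receptors 4 (22, 10, 7 and 4 when adjusted over the list alone); 1 immediate early gene fell (4 when adjusted over the list alone). Without sham replicate 1 the count was 159 (123 higher, 36 lower; 99 of the 106 among them), and with the spread of these 8 arrays alone it was 52, LYL1 not among them (adjusted p = 0.057, from 8.9e-04 over all alternatives); with array weights it was 235.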

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

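Of the tests below, those of the small RNAs, the FSL-1 exposure, the gradient, the exchange, the interaction without sham replicate 1, the interferon-stimulated list without CXCL10, chance for CXCL10 and the correlations of splits with the residual component were chosen only after the result was seen; the others were planned.

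Sham replicate 1 stood apart from the other sham arrays, with a median r to its group of 0.970, a score of -45.2 on the first principal component and an SD of 0.531 from its group over genes, against 0.239 to 0.332 for the other 15 arrays. A test argued against FSL-1 in that culture (FSL-1 genes deviated by a median of -0.188 of their response). Cells of another type stay open, although the highest median deviation among the 5 marker lists was 0.021 on the log2 scale. A marker above the median of all values in sham replicate 1 alone would not have met the filter of at least 4 arrays. NKG7, the brightest marker, had 9.57 ± 0.03 in all 4 sham arrays (SD), a level at which a small share of other cells would not show. Another yield of small RNAs stays open, with a gap of -0.22 to protein-coding genes that is exceeded in LysoPPC replicates 2, 3 and 4 (-0.75, 0.41 and 0.54) but lies outside the -0.12 to 0.13 of the other arrays outside the LysoPPC group, and so does a gradient among transcripts, as RNA quality or target yield could give: across genes the deviation correlated at 0.536 with the first residual component of the 8 FSL-1-treated arrays and at 0.122 or less with their other components. An exchange with LysoPPC replicate 3 cannot be told apart from this gradient, because sham replicate 1 lay nearer to LysoPPC replicates 1, 2 and 4 (0.363) but beyond the range of the other arrays, and LysoPPC replicate 3 lay 0.265 from sham replicates 2 to 4 and 0.299 from its own group. With sham replicate 1 and LysoPPC replicate 3 exchanged, LysoPPC minus sham called 1339 genes, against 0 with the labels as given. That count does not separate the exchange from the gradient. The gradient and exchange tests and their limits were set with those values in view, after those of cell type and small RNAs. The small-RNA limit was narrowed after its values were seen. Beyond FSL-1 exposure and markers of other cells no biological explanation was examined.

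The FSL-1 response was not shown to differ with LysoPPC, and an effect of LysoPPC that these arrays did not resolve stays open beside the technical explanations. No common scaling beyond chance was seen, since the slope of 0.972 lay inside the central 95% of regroupings, 0.886 to 1.09. This cannot argue against a scaling of a size that regroupings also give, which stays open. Low precision stays open: simulated changes of 1 on the log2 scale were recovered to 83.6% in both agents minus FSL-1, the comparison the planned limit was set for, but to 58.2% in the interaction, which bears on the response itself. Both shares come from independent noise with 200 changed genes and may be too high for these arrays. The 95% interval lay within 1 of 0 for 97.5% and 88.0% of genes in these comparisons. Whether sham replicate 1 hides a difference also stays open, because without it 0 genes passed in the interaction with limma but 1496 had an unadjusted p under 0.05, against 672 with it and 771 by chance, and the slope was 0.930.

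CXCL10 was lower after LysoPPC and FSL-1 than after FSL-1, by -0.78 (95% interval -1.18 to -0.38), which did not pass adjustment. In this comparison 4 of 4 arrays lay below the FSL-1 arrays, with the smallest possible exact permutation p = 0.0286. The rule for named genes did not take CXCL10 here, so that p is no independent test. Whether an interferon-type response as a whole was lower stays open: the mean of the other 33 interferon-stimulated genes differed by 0.021 (95% interval -0.05 to 0.09, exact permutation p = 0.486), but 2 of them were among the FSL-1 responders, so the list held little response to lose. Neither of these was lower, with IFIH1 at 0.01 (95% interval -0.43 to 0.45) and CXCL11 at 0.14 (-0.23 to 0.51), which goes against that explanation without excluding it on so few genes. A weaker response of the whole culture stays open. In 162 rising responders the level after both agents was lower than after FSL-1 by a median of 4.01% of the FSL-1 response. The quartiles were -7.9 and 13.6, and CXCL10 stood at 14.2%. This share leaves out the LysoPPC baseline and uses the FSL-1 arrays on both sides, so it does not measure the response lost. From the respective baselines CXCL10 rose by 5.48 without and 4.87 with LysoPPC. Chance among many genes is not excluded, with an adjusted p of 1.00 (0.9997).

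Other groupings of the same arrays were counted for each comparison. For FSL-1 minus sham 1 of 35 splits, the real one, gave as many genes (107, next 0), and for both agents minus LysoPPC likewise 1 of 35 (94, next 2). That is the smallest share this count can give, so it argues against chance for both without excluding it. All other splits mix arrays with and without FSL-1, which widens the spread and lowers their counts. For both agents minus sham 2 of 35 gave as many as the real 106, the other 1597, so chance cannot be excluded by this count. The genes themselves changed far beyond their spread in that comparison (CXCL10 by 4.70, SE 0.19, and NFKBIA by 2.62, SE 0.13). For LysoPPC minus sham (0 genes, highest other 1339) and both agents minus FSL-1 (0, highest other 1) all 35 of 35 gave as many, and for the interaction 100 of 100 (0, highest other 0); with a real count of 0 no other outcome was possible, so these counts test nothing. For the slope 67 of 100 groupings, the real one included, lay at least as far from 1 (0.972, farthest other 0.860), so chance is not excluded. The splits with 1339 and 1597 genes put sham replicate 1 with LysoPPC replicates 1, 2 and 4, or with LysoPPC+FSL-1 replicates 1, 3 and 4, and point to a structure of the samples. The split with 1339 genes is the exchange of sham replicate 1 and LysoPPC replicate 3 left open above. The first of these splits, which holds no FSL-1-treated array, correlated across genes at 0.568 with the residual component of the FSL-1-treated arrays; the second shares arrays with that component, so its correlation of 0.766 was partly fixed beforehand and is no evidence.

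A single array lay far from the other 3 of its group, by a gap test that marks about 1 in 20 groups by chance, in 14 of 232 gene levels (12 by chance), 4 of 20 array measures (1 by chance) and 6 of 108 list levels (5 by chance). In sham replicate 1 CXCR4 was at -0.41 from the mean of the other 3 on the log2 scale, IFNGR2 at -0.57, JUND at -0.72 and the heat shock list at 0.25. In LysoPPC+FSL-1 replicate 2 ACSL1 was at -0.24 and CEBPB at 0.36, the median r to its group was 0.987 and the score on the second component -0.695. CCL20 in sham replicate 4 was at 0.65 and NFKBIA at 0.64, and the erythroid and platelet list in sham replicate 2 at 0.11. MIR3935 was at 0.41 in sham replicate 3 and 0.21 in LysoPPC replicate 1, where ACSL1 was at 0.21. DUSP4 in LysoPPC replicate 4 was at -0.37, LYL1 in LysoPPC replicate 3 at 0.19, the heat shock list there at -0.13 and the NLRP3 list in LysoPPC replicate 2 at 0.27. In FSL-1 replicate 4 NFKBIA was at -0.08 and SNORD78 at -0.24, in FSL-1 replicate 2 the cytokine list at 0.17, and in LysoPPC+FSL-1 replicate 3 the TLR2 receptor list at 0.06.

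Outside the named genes, 15 of 14802 probe sets with no symbol or several passed in FSL-1 minus sham, all higher (5 with several genes, 10 unnamed here; largest change 2.72).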

How the results depend on the processing

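Among the alternatives, the floor of 4 on the log2 scale, the average LysoPPC effect and the lists without sham replicate 1 were chosen after the data were seen. Over all of them 0 results of called genes changed sign; of 103 calls of named genes 65 held under every alternative and 38 were lost under at least 1. Array weights (0.228 for sham replicate 1) gave 205 genes for FSL-1 minus sham (162 higher, 43 lower) and 235 for both agents minus sham (163 and 72). Fits on only the arrays compared gave 66 (65 and 1), 52 (51 and 1) and, for both agents minus FSL-1, 1 gene, against 98 for both agents minus LysoPPC. The cause was not tested. With 1 array left out, counts ran from 90 (without FSL-1 replicate 2) to 178 (without sham replicate 1) for FSL-1 minus sham, from 71 to 129 (without sham replicate 1) for both agents minus LysoPPC, from 74 to 159 (without sham replicate 1) for both minus sham, from 0 to 1 for LysoPPC minus sham, from 0 to 2 for both minus FSL-1 and from 0 to 0 for the interaction. The slope ran from 0.930 (without sham replicate 1) to 0.991 and the share of opposite sign from 43.9% to 57.4%. Responders with a change of 2-fold gave a slope of 0.983. The LysoPPC effect averaged over both FSL-1 conditions called 0 genes (757 at an unadjusted p under 0.05; SNORD78 -0.42, adjusted p = 0.117).

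The deviations showed no general pairing by replicate number: same-numbered arrays had a median correlation of 0.0084 (-0.271 to 0.439), 7 of 24 pairs were over 0.1, and 5 of 16 arrays correlated best with their own number. The highest value, 0.439, was that of sham replicate 1 with FSL-1 replicate 1. LysoPPC replicate 1 correlated at 0.2245 with sham replicate 1 and at 0.177 with FSL-1 replicate 1. LysoPPC+FSL-1 replicate 1 correlated with these arrays at 0.0185 (sham), -0.0016 (LysoPPC) and -0.0195 (FSL-1). A pairing of some same-numbered arrays, sham replicate 1 among them, is not excluded by these values. With the replicate block 105, 93 and 98 genes passed in FSL-1 minus sham, both agents minus LysoPPC and both minus sham, 0 in the other contrasts, the slope was 0.968, CCL4 passed in both agents minus LysoPPC (adjusted p = 0.0264), and the cholesterol list held in LysoPPC minus sham (adjusted p = 0.0421). Calls of named genes were also lost with this block. They were TLR2 and ADCY1 in FSL-1 minus sham (adjusted p = 0.0642 and 0.0973) and DUSP4 in both agents minus LysoPPC (0.0518). In both agents minus sham they were FBXO10, DOK3, ORC1 and PPP1R15A (adjusted p = 0.0508, 0.0779, 0.0844 and 0.0838). Signal over background limits genes such as CXCL10 in sham cells, whose rise from near background may be understated.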

Other observations

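The correlation of the LysoPPC difference with the residual component, its use as a covariate, and the average LysoPPC effect were chosen only after the result was seen.

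Of the genes named for the smallest p in the LysoPPC comparisons, BCL2A1 also passed in FSL-1 minus sham. BCL2A1, an inhibitor of apoptosis, had 4.69 ± 0.27 in sham, 5.39 ± 0.26 in LysoPPC, 6.01 ± 0.14 in FSL-1 and 6.17 ± 0.16 in LysoPPC+FSL-1 cells (SD, n = 4), and its rise with FSL-1 passed (1.31, adjusted p = 5.4e-05). The chemokine gene CCL1 had 1.33 ± 0.13, 1.25 ± 0.12, 1.86 ± 0.10 and 2.79 ± 0.63 in the same order (SD, n = 4). It passed against LysoPPC alone (1.54, adjusted p = 5.7e-04) and not in FSL-1 minus sham (0.53, adjusted p = 0.564), and its interaction of 1.02 did not pass (adjusted p = 1.00). SNORD78 was lower with LysoPPC without FSL-1 (-0.49) and with it (-0.35), neither past the threshold, nor was the average of both (-0.42, adjusted p = 0.117).

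Without sham replicate 1, 2806 genes (18.2%) had an unadjusted p under 0.05 in LysoPPC minus sham, against 983 with it, yet 1 gene passed adjustment with limma. Across genes, which are not independent replicates, that difference correlated at 0.525 with the first component of the deviations of the FSL-1-treated arrays from their own group means, which holds no sham or LysoPPC array and no group difference. With the score on that component as a covariate 1359 genes were at an unadjusted p under 0.05. The score came from the full expression values, so it also carries any LysoPPC difference along the component. The lower number was thus partly built in and is no evidence for a gradient. By the correlation of 0.525, part of the difference may follow the gradient that bears on sham replicate 1 (correlation 0.536). These arrays do not separate it from an effect of LysoPPC.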
